A study of Homo sapiens with 4 samples.

How the data were processed

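TEAD4 binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in a human trophoblast stem (HTS) cell line, a line that proliferates in culture and serves as a model of the placental trophoblast. The series holds 3 TEAD4 ChIP libraries and 1 input library. Per the labels' protocols, nuclei of formaldehyde-crosslinked cells were sonicated, an anti-TEAD4 antibody was used for the precipitation, and size-selected libraries were amplified by PCR and sequenced on an Illumina NovaSeq instrument. The labels name 3 replicates but do not say whether they came from separate cultures, so the spread between them may be technical.

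Each ChIP library came with its own peak list. Per the submitters' processing notes, reads were converted with bcl2fastq, aligned with Bowtie2 2.3.4.3 to GRCh38, and peaks were called with MACS2 2.1.2. Per the file headers, narrow peaks were called from paired-end fragments for each library on its own at a q-value threshold of 0.05, with 1 duplicate kept per position and the same input library as the control of all 3 calls. The pileup is a deposited signal, the number of fragments covering the peak summit after duplicate removal. The fold enrichment is a deposited ratio of that pileup to the local background expected from the scaled input. The deposited −log10 p-value and −log10 q-value are those MACS2 assigned to each peak. These values belong to the authors' peak calls and were used to describe, rank or filter peaks. Since the control is shared, its local depth and its chance enter all 3 lists, and part of their overlap may come from it; the reads that a simulation of this needs were not used here. The input library entered only as that background.

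The headers give the depth. The ChIP libraries held 98539786, 91811211 and 109022813 fragments for replicates 1, 2 and 3, of which 5156801, 8755278 and 5605660 were kept after duplicate removal (5.23%, 9.54% and 5.14%). The input held 138026242 fragments, of which 48679537 were kept. At this depth a peak could be called from few fragments: the smallest summit pileups were 3, 5 and 4, and 51.2%, 6.05% and 22.2% of peaks had a pileup of 5 or less.

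Positions are 1-based coordinates of GRCh38. Peaks on chromosomes 1 to 22 and X were used, and peaks on Y, mitochondrial and unplaced sequences were left out. Peaks of the 3 libraries that overlapped by at least 1 bp were merged into regions, and a region with a peak of each library is called here a region of all 3 libraries. Chance was measured by 100 seeded shuffles that placed each library's peaks at random within their own chromosome. A second set of 100 shuffles, added after the data were seen, moved each peak by 10 to 100 kb. This keeps the crowding of peaks on a broader scale than the moves, but not finer crowding. Strength was compared within each library between peaks in regions of all 3 libraries and peaks found in that library alone. With 3 libraries the smallest two-sided exact sign-flip p is 0.25, so no p is given for it. Spearman correlations of fold enrichment are across overlapping peaks, which are not independent replicates.

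Genes came from a RefSeq gene table of GRCh38.p14 that gives the start and end of each gene without its strand or exons. The table also lists 679 genes, 153 of them protein-coding, with positions on unlocalised or alternate sequences under a chromosome's name. They were recognised by the order of the table, in which positions start anew after those of a chromosome, and were left out; none was on a gene list. The planned distance to transcription start sites was therefore replaced by the distance to either end of a gene, and the planned split into exons and introns by inside or outside of a gene. The planned test of sequence motifs at summits was not run, because no genome sequence was used here. Of 517 distinct symbols on the gene lists, 515 matched; TDGF1 and TRBC1 did not. For each of 15 gene lists, the share of genes with a region of all 3 libraries within 10 kb of an end was set against all other protein-coding genes (19821 in total) by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 15 lists. The lists covered trophoblast stem cells and cytotrophoblast, syncytiotrophoblast, extravillous trophoblast, YAP/TAZ-TEAD targets, Hippo pathway components, cell cycle, EGF receptor and MAPK signalling, WNT signalling, actin cytoskeleton and adhesion, pluripotency, placental stroma and endothelium, blood cells, neurons, hepatocytes and ribosomal proteins. Intervals of shares are exact 95% binomial intervals and cover counting error only.

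The groups, tests, lists, and the rule for named genes and most of the other settings were set before the data were examined. The rule names the 10 regions of all 3 libraries with the highest mean within-library percentile of fold enrichment, up to 4 members of each list with such a region within 10 kb, and 23 genes whatever their values. The other settings tried were stricter thresholds on q and fold, other rules of overlap, equal numbers of peaks per library, support by at least 2 libraries, other distances, protein-coding genes only, random lists matched on gene length and number of transcripts, other strength measures, and leaving out each replicate. Chosen after the data were seen were the crowded bins (1 Mb bins with 10 or more regions of all 3 libraries), the strong sites (regions outside these bins with a fold over 30 in any library), and the settings without the crowded bins or with regions anywhere in the gene span.

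Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The code of the merging and list test was run on simulated data. Of 2000 planted shared regions, 100% were recovered in all 3 simulated libraries, a planted gene list passed, and 0 of 14 null lists did. The planted regions overlapped by construction, and the planted list was longer than the real lists. This run therefore checks the code and says nothing of the power of the tests.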

Results

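TEAD4 ChIP-seq was used in human trophoblast stem (HTS) cells to find the genes that TEAD4 binds. TEAD4 is a DNA-binding transcription factor of the TEA domain family and a partner of the Hippo pathway coactivators YAP1 and WWTR1 (TAZ). The data were 3 ChIP libraries of a single group, each with peaks called against the same input library, so the comparisons are between libraries and against chance, not between conditions. On chromosomes 1 to 22 and X the lists held 93146 peaks for replicate 1, 35955 for replicate 2 and 58990 for replicate 3. These rested on 5156801, 8755278 and 5605660 fragments kept after duplicate removal. The median fold enrichment over input was 4.12, 4.75 and 5.02, and the highest was 335, 298 and 43.3. At most 18 peaks of any pair of libraries had identical coordinates.

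The first question was which sites TEAD4 occupied in every library. Merging the lists gave 142826 regions, of which 12879 (9.02%) held a peak of all 3 libraries, 15292 of 2 libraries and 114655 (80.3%) of 1 library. The count of 12879 depended on the settings: it was 4155 with a fold of at least 5 and 21555 without replicate 2. The latter asks for a peak of only the 2 remaining libraries, a looser rule than a peak of all 3. With support by at least 2 of the 3 libraries the count was 28171. Random placement within chromosomes gave a mean of 22.3 regions of all 3 libraries and at most 35 over 100 shuffles. Moving each peak by 10 to 100 kb, a control added after the data were seen, gave a mean of 2401 and at most 2505. The regions were concentrated in few places. 79 bins of 1 Mb, chosen after the data were seen for holding 10 or more such regions, made up 2.61% of the span of the chromosomes and held 10363 (80.5%) of the regions of all 3 libraries. The fullest was chromosome 20, 27000001 to 28000000, with 464 regions, followed by chromosome 6, 59000001 to 60000000, with 405. These bins occurred on all 23 chromosomes analysed, mostly at or beside the centromere, and held the midpoints of 45 protein-coding genes. Outside them 2516 regions of all 3 libraries remained, against a mean of 8.87 and at most 17 for the moved peaks.

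**Figure D1:**
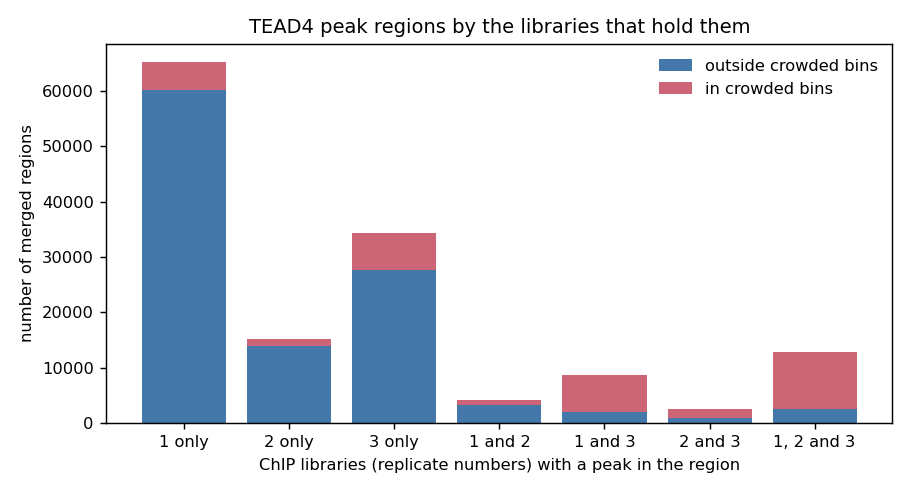
Number of merged TEAD4 regions (vertical axis) by the replicate libraries with a peak in them (horizontal axis), with regions in the 79 crowded 1 Mb bins in red and all others in blue. Of the 12879 regions of all 3 libraries, 10363 lay in the crowded bins, while 60130 of the 65253 regions of replicate 1 alone lay outside them.

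**Figure D2:**
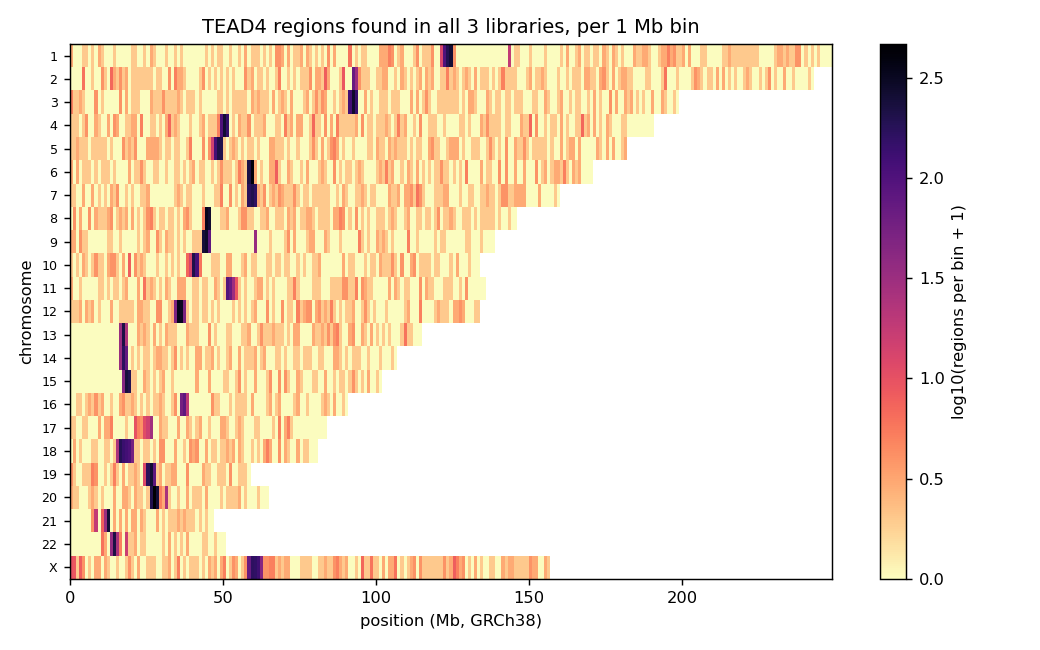
Regions of all 3 libraries per 1 Mb bin, on a colour scale of log10(regions per bin + 1), along chromosomes 1 to 22 and X (vertical axis) by position in Mb of GRCh38 (horizontal axis). Each chromosome has a dark stretch of crowded bins, up to 464 regions in a bin on chromosome 20.

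The libraries shared between 19.0% and 49.6% of their peaks pairwise. Of the peaks of replicate 1, 19.0% overlapped a peak of replicate 2 and 25.4% a peak of replicate 3. For replicate 2 these shares were 49.6% with replicate 1 and 46.1% with replicate 3, and for replicate 3 they were 37.4% with replicate 1 and 26.5% with replicate 2. Over all peaks, the highest share was 16.4% for peaks moved by 10 to 100 kb and 2.26% for peaks placed at random within chromosomes. Outside the crowded bins the shares were lower, at 8.44% and 6.71% for replicate 1, 27.9% and 16.6% for replicate 2 and 13.7% and 10.4% for replicate 3, in the same order. No chance level was computed for these shares, and the 16.4% includes the crowded bins, so it is no measure for them. Peaks in no other library made up 70.1%, 42.0% and 58.1% of replicates 1, 2 and 3. Across overlapping peaks, fold enrichments had a Spearman correlation of 0.670 between replicates 1 and 2, 0.423 between replicates 1 and 3 and 0.448 between replicates 2 and 3. Outside the crowded bins these were 0.921, 0.662 and 0.659.

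By median fold over all bins together, regions of all 3 libraries were not stronger than those of a single library in every replicate. The log2 ratio of their median folds was 0.32 ± 0.31 (SD, n = 3 libraries), with values of 0.54, −0.04 and 0.45 in replicates 1, 2 and 3, so over all regions the direction differed between libraries. The value of replicate 2 mixed bins of unlike fold. Of its 14174 peaks in regions of all 3 libraries, 11608 lay in the crowded bins, against 1202 of its 15117 peaks found alone. By median pileup, regions of all 3 libraries were higher in replicate 2 too (19 against 8). Outside the crowded bins the ratio was 2.69 ± 1.54 (SD, n = 3) and positive in all 3 libraries, at 3.68, 3.47 and 0.91. There the median fold in regions of all 3 libraries was 48.7, 54.3 and 8.16, against 3.79, 4.91 and 4.34 in regions of a single library. Inside the crowded bins the ratio was also positive in all 3 libraries, at 0.24, 0.09 and 0.36, with medians of 5.28, 4.39 and 5.88 in regions of all 3 libraries against 4.49, 4.12 and 4.59 in regions of a single library.

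**Figure D3:**
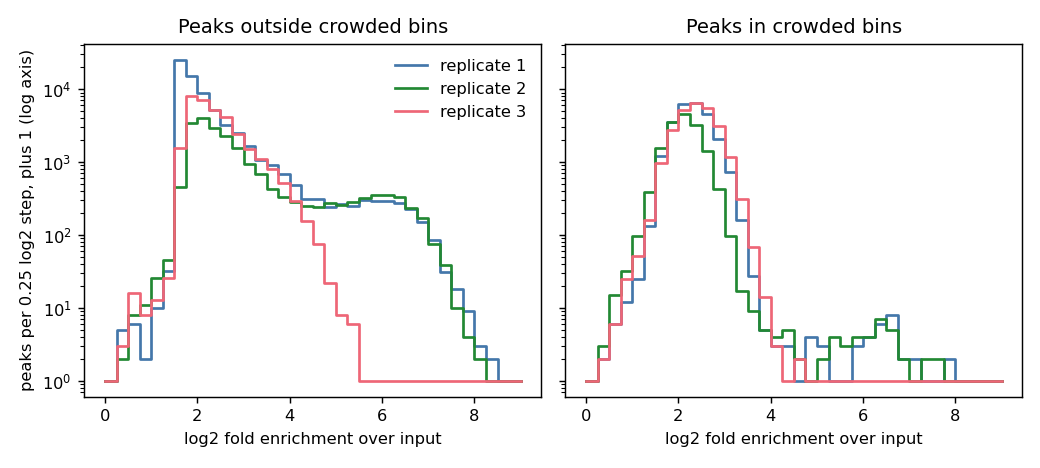
Number of peaks per 0.25 step of log2 fold enrichment over input, plus 1, on a log axis (vertical), against log2 fold enrichment (horizontal) for the 3 replicate libraries, outside (left) and inside (right) the crowded bins. Outside these bins replicates 1 and 2 have a second set of strong peaks, which reaches a fold of 335 and 298, while replicate 3 ends at 43.3.

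Most sites with a high fold lay outside the crowded bins, and most of these were shared by replicates 1 and 2. A fold over 30 in any library, a threshold chosen after the data were seen, held for 2695 regions outside the crowded bins and 26 inside them. Of the 2695 outside, called strong sites here, 2661 (98.7%) had peaks in replicates 1 and 2, 1695 had peaks in all 3 libraries, 966 had them in replicates 1 and 2 but not 3, and 32 had a peak in 1 library. Over the sites with a peak in the library, the median fold was 55.3 in replicate 1 (2682 sites), 60.5 in replicate 2 (2671) and 10.4 in replicate 3 (1700). The 995 sites without a replicate 3 peak had a median fold of 36.5 in replicate 1, against 71.4 for the 1700 with one. The log2 ratio of replicate 1 over replicate 2 had a median of −0.11 ± 0.55 (SD over 2661 sites), and that of replicate 1 over replicate 3 a median of 2.77 ± 0.71 (SD over 1697 sites).

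The 10 regions with the highest ranks of fold in all 3 libraries lay 8.29 to 1056 kb from the nearest end of a protein-coding gene. For regions of all 3 libraries placed at random the median distance was 61.7 kb, so these distances are not shown to be unusual. The highest ranked was on chromosome 4, 180390217 to 180391143, between genes, with folds of 276, 238 and 38.0 in replicates 1, 2 and 3. The nearest end of a protein-coding gene, that of the teneurin gene TENM3, was 1056 kb away. Of the 10 regions, 4 lay inside protein-coding genes. They were in AGBL4 (chromosome 1, 49947952 to 49948614; folds 246, 246 and 33.3), CPNE4 (chromosome 3, 131978045 to 131978624; 258, 198 and 25.9), PRR5L (chromosome 11, 36350903 to 36351812; 195, 163 and 31.7) and the mitochondrial carrier gene SLC25A30 (chromosome 13, 45423509 to 45425730; 168, 163 and 31.2). The region nearest to S1PR1, which encodes a receptor for sphingosine-1-phosphate, lay 10.6 kb from it on chromosome 1, 101252882 to 101253958, with folds of 159, 211 and 28.1. Regions near TPBG, the trophoblast glycoprotein gene, and SNRPN, an imprinted gene, lay 56.0 and 55.9 kb away, on chromosome 6, 82306701 to 82307008, and chromosome 15, 24767132 to 24767702. The remaining regions were nearest to LOC124901178, at 128 kb on chromosome 5, 28796918 to 28797767, and to SPIN4, at 382 kb on chromosome X, 62964378 to 62965479. The last lay in a crowded bin, with folds of 248, 184 and 26.7.

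Regions of all 3 libraries lay near gene ends less often than the same regions placed at random. Of the 12879 regions of all 3 libraries, 0.722% (95% interval 0.583% to 0.884%) had their midpoint within 1 kb of an end of a gene and 10.01% (9.50% to 10.5%) lay inside genes, against means of 6.27% and 54.4% over 100 shuffles. Without replicate 3 the shares were 1.3% and 16.8% of 17313 regions. The deficit rested largely on the crowded bins. Outside them 3.06% (2.42% to 3.81%) lay within 1 kb of a gene end, against 5.95% for the shuffles (4.93% to 7.47%), and 50.2% (48.2% to 52.1%) lay inside genes, against 54.9% (52.2% to 57.4%). Of the strong sites, 3.49% lay within 1 kb of a gene end and 49.9% inside genes. Regions of a single library were also below the shuffles near gene ends, at 4.66%, 5.05% and 4.35% for replicates 1, 2 and 3. Their shuffles gave 6.03%, 6.26% and 6.18%, so a deficit was not particular to regions of all 3 libraries. No list of regions prone to false signal was used to filter peaks. Over all peak summits of each library, 3.12% ± 0.42 (SD, n = 3) lay within 1 kb of a gene end and 35.2% ± 5.26 inside genes, against 6.15% and 54.7% for the shuffles.

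Few genes of the trophoblast and Hippo lists had a region of all 3 libraries nearby. Within 10 kb of an end, 400 of 19821 protein-coding genes (2.02%) had such a region, and as neighbouring genes share regions their nearest ones were 319 distinct regions. The counts were 0 of 40 genes for trophoblast stem cells and cytotrophoblast (upper 95% limit 8.81%), 1 of 43 for syncytiotrophoblast, 0 of 36 for extravillous trophoblast, 0 of 22 for YAP/TAZ-TEAD targets and 0 of 38 for Hippo pathway components. The syncytiotrophoblast member was HOPX, a homeodomain-only gene, with a region 4.16 kb away on chromosome 4, 56685864 to 56686224, and folds of 63.0, 122 and 7.07. For cell cycle the count was 1 of 53: CENPE, a kinetochore motor gene, held a region inside it with folds of 27.7, 56.5 and 5.79. For actin cytoskeleton and adhesion it was 2 of 38. These were the small GTPase gene RHOB, with a region 0.736 kb away and folds of 6.32, 8.37 and 5.27, and the integrin gene ITGA3, with a region inside it and folds of 55.6, 65.2 and 4.94. EGF receptor and MAPK signalling had 0 of 36, WNT signalling 0 of 32 and pluripotency 0 of 23. Among the lists of other cell types, hepatocytes had 2 of 30 (APOB and HNF4A), placental stroma and endothelium 1 of 24 (CDH11), blood cells 1 of 31 (CD3G) and neurons 0 of 30, and ribosomal proteins had 0 of 52. By two-sided Fisher's exact test 0 of the 15 lists differed from other genes after Benjamini-Hochberg adjustment (each adjusted p = 1), and 0 did at an unadjusted p under 0.05. With these counts a list's share could not be told from 2.02% unless it was several times higher.

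**Figure D4:**
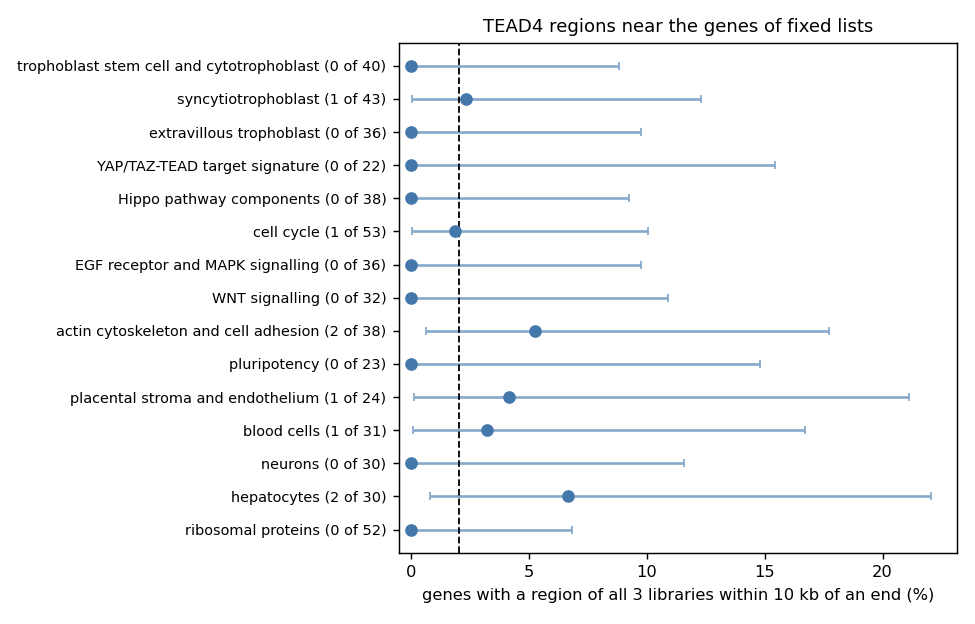
Percentage of the genes of each fixed list with a TEAD4 region of all 3 libraries within 10 kb of an end (horizontal axis), with exact 95% binomial intervals as bars and the counts beside the list names. The dashed line is the mean share of all other protein-coding genes, 2.02%, and the intervals of all lists include it.

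None of the 23 genes named in advance had a region of all 3 libraries within 10 kb of either end, and 1 had it within 50 kb. Distances in this paragraph are to the nearest end of a gene. That gene was CDX2, a homeobox gene of the trophectoderm, with a region 25.2 kb away on chromosome 13, 27934366 to 27935702, and folds of 54.2, 63.5 and 10.1 in replicates 1, 2 and 3. About 8.7% of protein-coding genes had a region of all 3 libraries within 50 kb, so 1 of 23 is not above the background. The median distance from the 23 genes to such a region was 668 kb, against 488 kb for all protein-coding genes. CCN2, a widely used YAP-TEAD target gene, was the only one of the 23 with a region of 2 libraries within 10 kb of an end. About 7.0% of protein-coding genes had a region of at least 2 libraries at such a distance. The count among the 23 is therefore not above the background either. That measure misses regions deeper inside a gene. A region of replicates 2 and 3 lay inside TP63, 66.6 kb from an end, with folds of 3.72 and 4.58. The region near CCN2 lay 8.35 kb away on chromosome 6, 131939642 to 131939829, with folds of 25.8 in replicate 1 and 22.1 in replicate 2. Regions of replicates 1 and 2 without replicate 3 also lay 16.3 kb from VGLL1, a TEAD cofactor gene (chromosome X, 136573093 to 136573721, folds 67.7 and 59.9), and 32.8 kb from CGA (folds 18.3 and 31.5). Another lay inside the integrin gene ITGA6, 23.5 kb from an end (chromosome 2, 172450791 to 172451033, folds 44.6 and 43.3). The WNT co-receptor gene LRP5 held a further region 39.8 kb from an end (chromosome 11, 68409068 to 68409453, folds 43.1 and 59.3). All of these were strong sites. Of protein-coding genes outside the trophoblast stem cell list, 9.99% had a strong site within 50 kb of an end. For GATA3, a trophoblast transcription factor gene, the nearest region of all 3 libraries was 193 kb away, with folds of 101, 120 and 20.7. At TEAD4 itself it was 459 kb away, with folds of 4.73, 4.96 and 7.56. None of the libraries had a peak within 10 kb of either end of TEAD4. The nearest peaks of replicates 1, 2 and 3 lay 36.5, 28.0 and 26.6 kb from an end. Whether they lay inside the gene was not determined.

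Single-library peaks near these genes were frequent. Of the 23 genes, 15 had a peak of at least 1 library within 10 kb of an end, 9 of them of exactly 1 library. Among all protein-coding genes 68.4% had such a peak. Replicate 1 had a peak within 10 kb of 12 of the 23 genes and of 48.5% of all protein-coding genes, replicate 2 of 5 genes and 21.2%, and replicate 3 of 5 genes and 31.7%. The best such peak had a fold of 3.803 in replicate 1 and 7.71 in replicate 2 at TFAP2C, 3.00 and 4.10 at GATA3, and 5.31 in replicate 1 at YAP1. GCM1, the transcription factor gene of syncytiotrophoblast formation, had folds up to 8.37 in replicate 1 and 16.6 in replicate 2, and ELF5 had a fold of 4.44 in replicate 3. LRP5 had peaks of all 3 libraries within 10 kb of an end that did not share a region.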

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

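Peaks on unplaced or unlocalised scaffolds stood outside all comparisons. They are given because they are signal in a part of the data that was not analysed; no control level was set against them. Replicate 1 had 426 such peaks, replicate 2 had 274 and replicate 3 had 496, which is 0.454%, 0.754% and 0.831% of their lists. Their median fold was 4.15, 3.69 and 4.33. No group of 4 or more samples and no contrast of groups existed for a test of a sample or an effect that stands apart.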

How the results depend on the processing

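The settings without the crowded bins or with regions anywhere in the gene span were chosen after the data were seen; the others were planned. The count of regions of all 3 libraries (12879) was 28171 with support by at least 2 libraries, 6330 with −log10 q of at least 5, 4155 with a fold of at least 5, 6778 with 50% reciprocal overlap, 6564 with summits within 100 bp, and 2516 without the crowded bins. Leaving out a replicate gave 15435 to 21555 regions, the highest without replicate 2; a pair of libraries asks for less overlap than 3. The mean pairwise share of 34.0% was 13.9% without the crowded bins. The mean correlation of folds, 0.514, was 0.768 with pileup, 0.695 with −log10 q of at least 5 and 0.747 without the crowded bins. The log2 strength ratio of 0.32 was 1.48 with pileup, 1.22 with −log10 q and 2.69 without the crowded bins, and 0.10 to 0.39 with a replicate left out. Location is given as the observed share over that of the shuffles, near gene ends (0.115) and inside genes (0.184). These ratios were 0.193 and 0.265 with −log10 q of at least 5, 0.187 and 0.286 with at least 2 libraries, 0.0552 and 0.172 with protein-coding genes only, and 0.510 and 0.916 without the crowded bins. With a replicate left out they were 0.118 to 0.209 and 0.194 to 0.308. All of these ratios stayed below 1. Except where stated, the cause was not tested. The number of gene lists past the adjusted threshold was 0 under each setting run. By Fisher's exact test, the smallest unadjusted p was 0.0190 for hepatocytes without replicate 2 (adjusted p = 0.285), and the smallest adjusted p values ranged from 0.285 to 1. The planned motif tests were not run. No paired analysis was possible because the replicate numbers belong to a single ChIP group. In replicate 1, 51.2% of peaks rested on a pileup of 5 or less; whether depth set the length of the lists was not tested.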

Other observations

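The tests below were chosen after the patterns were seen, except those of genes that hold many strong sites and of symbol stems, which were set before their results were seen. The genes in this paragraph were also chosen after their values were seen. Among genes with a region of all 3 libraries within 10 kb, the highest ranks of fold were at SLC25A30, at EPRS1 and the zinc and manganese transporter gene SLC30A10, which share a region (chromosome 1, 219960229 to 219961072; folds 184, 172 and 23.01 in replicates 1, 2 and 3), and at VSIG4, SNRNP35 and ZNF430. A region inside the interferon gamma receptor gene IFNGR1 (chromosome 6, 137199245 to 137199669) had folds of 116, 122 and 16.1. The MBD3L paralogs on chromosome 19 had regions 1.37 to 1.45 kb away; reads of these near-identical copies can be misplaced, so the values are uncertain.

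Strong sites were also counted within 50 kb of an end of the genes of the fixed lists. Of the 40 trophoblast stem cell and cytotrophoblast genes, 7 had one (17.5%, 95% interval 7.34% to 32.8%), against 9.99% of other genes; they were ITGA6, LRP5, CDX2, KLF5, SPINT1, PAGE4 and VGLL1. The hypothesis that strong sites lie near these genes more often gave an adjusted p of 0.838 by Fisher's exact test over 15 lists. That met the outcome set down against the hypothesis, an adjusted p of 0.05 or more, but the interval includes both the share of other genes and shares of several times that, so the count is too small to exclude it. Of the 36 extravillous trophoblast genes 0 had a strong site (Fisher's exact test, unadjusted p = 0.0459, adjusted p = 0.688). Hippo pathway components had 5 of 38 (13.2%), among them FAT1, and YAP/TAZ-TEAD targets 2 of 22 (9.09%), while the unrelated lists of ribosomal proteins and hepatocytes had 7 of 52 (13.5%) and 4 of 30 (13.3%).

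Strong sites were not concentrated in single genes beyond the threshold. Given gene length, 0 of 19821 protein-coding genes held more strong sites than expected at an adjusted p under 0.05 by a Poisson test, and 235 did at an unadjusted p under 0.05. The smallest p of this exact Poisson test belonged to LUZP2, with 6 sites where 0.521 were expected (adjusted p = 0.352). Of 97 groups of genes with a shared symbol stem, 0 were over-represented near regions of all 3 libraries at an adjusted p under 0.05 by Fisher's exact test, and 6 had an unadjusted p under 0.05. The smallest adjusted p was 0.160, for RNF, with 7 of 85 genes at 6 distinct regions; the test treats genes that share a region as independent. Neither count shows that no gene or group departs from chance.

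Regions of all 3 libraries crowded into 79 bins of 1 Mb, mostly at centromeres. Chance overlap of crowded peaks gave fewer regions than were found: peaks moved by 10 to 100 kb gave at most 2482 there against 10363. The bins were chosen by the observed regions, which favours the observed count. Over all chromosomes, with no choice of bins, the moved peaks gave at most 2505 against 12879. The moves break any crowding finer than their own scale, so chance overlap within such finer crowding was not tested. Reads of repeated sequence piling up in ChIP and input alike are a candidate explanation: the background implied by the deposited fold and pileup was 3.62 ± 0.46 (SD, n = 3) times higher at peaks inside these bins than outside, and higher in each library. That calculation assumes the pseudocount that MACS2 adds, and its 3 values share the input, so they are not independent. A raised background was not particular to these bins. Its median at the strong sites was 0.583, 1.08 and 0.979 fragments in replicates 1, 2 and 3. Over all peaks outside the bins it was 0.315, 0.664 and 0.461, and over those inside 1.17, 2.68 and 1.44. No biological explanation was tested, since the design holds a single ChIP group.

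Of the peaks of replicates 1, 2 and 3, 70.1%, 42.0% and 58.1% lay in no other library. Unequal list lengths are not the whole of this, because with lists of equal length, taken by −log10 q, 46.2% to 50.3% of each list still lay in no other library; they may account for part of the higher shares of replicates 1 and 3. Weak peaks near the calling threshold may account for another part. Outside the crowded bins the share found in another library was 49.7 ± 19.5 (SD, n = 3) percentage points higher in the strongest than in the weakest decile of fold. The deciles were cut over all peaks of a library, so their parts outside the bins are unequal. In replicate 2 the weakest held 909 peaks there and the strongest 3561. Over all peaks the weakest decile of replicate 2 had 73.8% in another library and its decile 9 had 38.9%. Outside the bins these were 27.2% and 32.8%, so that order rested on the crowded bins. The strongest decile of replicate 2 outside the bins had 96.0%, but those of replicates 1 and 3 had 52.5% and 37.8%. In replicates 1 and 3, peaks weak by fold are therefore not the whole of it. Peaks were called by q-value and not by fold, so nearness to the calling threshold itself was not measured. Differences between cultures stay open, and no biological explanation was tested.

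Strong sites had lower folds in replicate 3, with a median log2 ratio of 2.77 of replicate 1 over 3 at the sites with both peaks; they were chosen by a fold that few replicate 3 peaks reach, which fixes part of this. Chosen by replicate 2 alone (2549 sites), the ratio was 2.78, and 879 sites had a peak of replicate 1 and not of 3; among the 1000 strongest regions of replicate 3, 500 had a replicate 1 peak, with a ratio of 2.42. A single lower scale of replicate 3 for all regions is argued against by 11197 regions of replicates 1 and 2 in bins crowded in these libraries, whose folds, lowered by 2.77 on the log2 scale, would fall below that of any replicate 3 peak: 91.7% held one, against at most 43.3% with replicate 3 peaks moved. A higher background of replicate 3 stays open: the implied background over the genome level had a log2 ratio of −0.031 of replicate 3 over 1, but the shared input fixes this near 0, and it says nothing of non-specific signal in the ChIP. A lower yield of the precipitation or a difference between cultures stays open too, and no biological explanation was tested.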
